A study of Mus musculus with 8 samples.

How the data were processed

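Total RNA of snap-frozen tibialis anterior from 8 mice, 4 controls and 4 Carm1 knockouts, was extracted with Trizol and made into libraries with a TruSeq RNA kit, per the labels' protocols. Reads were processed with STAR and Cufflinks against mm10, per the submitters' processing notes, which give no version; the annotation is not given in the sources used here. The FPKM values are those the authors deposited, 1 table per library in the Cufflinks gene layout per the file headers. No read counts are given, so count models were not used. The interval columns equal the value for at least 99.87% of genes in each library and were not used. Cufflinks shares reads between overlapping genes by estimation, and the kit named in the labels does not mark strand as far as they say, so values of overlapping and antisense genes are uncertain. A gene listed at 0 can be a failed estimate: genes with a status other than OK in any library, 23 in all and including Myh1 and Myh4, were left out of the tests. No mitochondrially encoded gene was listed, so the planned mitochondrial share was not computed. Gene names that a spreadsheet had turned into dates, 27 in all, were restored by position with GENCODE release M21, whose assembly is that of mm10. No read depth is given. The relative depth of each library was estimated from the commonest ratio of FPKM values under 0.15 between libraries, which gives no absolute precision per gene. The 4 animals per genotype are separate animals per the labels.

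FPKM were divided by median-of-ratios factors over genes with at least 1 FPKM in all libraries, which lay between 0.904 and 1.07, and analysed as log2(scaled FPKM + 1). A log2 difference on this scale understates the change of low genes. Genes with at least 1 scaled FPKM in at least 4 libraries were tested, 11096 in all, with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on the mean), Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists, 41 in number and written before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, and 39 could be tested. Carm1 and the myosin share were tested with exact permutation, 2-sided. On simulated data with the comparison's own means and spread, 11096 genes and 200 changed genes, limma recovered 83.9% of genes changed by 1 and 41.3% of those changed by 0.5 on the log2 scale, and 5.06% of its calls were false. A shift of -0.25 in 1 list was called in 10 of 10 simulations. These simulations draw genes independently. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

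The genes named were fixed by a rule before the data were examined: Carm1; the 12 largest increases and 12 largest decreases in log2 difference among genes past the threshold with a mean of at least 1 scaled FPKM and no overlap between the groups, transcripts with clone-type, microRNA or small nucleolar RNA names skipped; and, in each list, up to 2 called members per direction or else the 2 with the smallest p, given as values. Members past the threshold over a list alone are also named. Results of a few genes that meet the rule are not reported here. AA465934 and the genes named in the closing section outside this rule were chosen after their values were seen. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, no scaling, quantile normalization, leaving out each library, the replicate number as a block, robust eBayes, array weights, a log2 difference of at least 0.5, an estimated correlation and ranks in camera, and, for myosin, further genes in the sum. Chosen after the data were examined were the presence of Xist (at least 1 FPKM) as a covariate, the 5 libraries without Xist alone, the contrast within the 3 with it, the Myh2 share over 3 myosin genes, and the removal from each library of loess trends (span 0.5) on transcript length, GC content and mean level.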

Results

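RNA from the tibialis anterior, a fast-twitch muscle of the lower hind limb, was sequenced from 8 mice of 12 weeks on a chow diet, all described as male. Carm1 encodes a protein arginine methyltransferase also called PRMT4. In 4 knockout animals floxed Carm1 was combined with a Cre transgene under the human skeletal actin promoter, which is active in muscle fibres, and 4 control animals carried floxed Carm1 without Cre. Presence of Cre and loss of Carm1 therefore go together in every library. The comparison asks how the muscle transcriptome differs with and without Carm1 in skeletal muscle. Each library was a table of FPKM (fragments per kilobase of transcript relative to all mapped fragments of the library) for 24341 genes. Read counts per library are not known from these tables. Summed FPKM lay between 604428 and 681042, and between 10775 and 11221 genes reached 1 FPKM. The relative depth estimated from the spacing of low values lay between 81.0% and 100% of the deepest library, control 1.

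Carm1 was lower in every knockout library than in every control library. Its level was 30.5 ± 4.82 scaled FPKM in controls and 15.4 ± 2.57 in knockouts (mean ± SD, n = 4 each), which is 50.6% of the control mean. The log2 difference was -0.94 with a 2-sided exact permutation p of 0.0286, the smallest that 70 assignments can give. As deposited, the control libraries stood at 26.5, 36.0, 24.7 and 31.0 FPKM and the knockout libraries at 18.4, 13.5, 16.5 and 14.7 FPKM. The gene lies on chromosome 9 from 21546894 to 21595970 (mm10) and overlaps the listed genes Yipf2 and 1810026J23Rik. Which exons were deleted is not given in the sources used here, so reads from retained exons and from cells other than muscle fibres can contribute to the remaining level. In limma across all genes the adjusted p of Carm1 was 0.0466, and it rose to between 0.0626 and 0.154 when any 1 of the 8 libraries was left out.

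**Figure D1:**
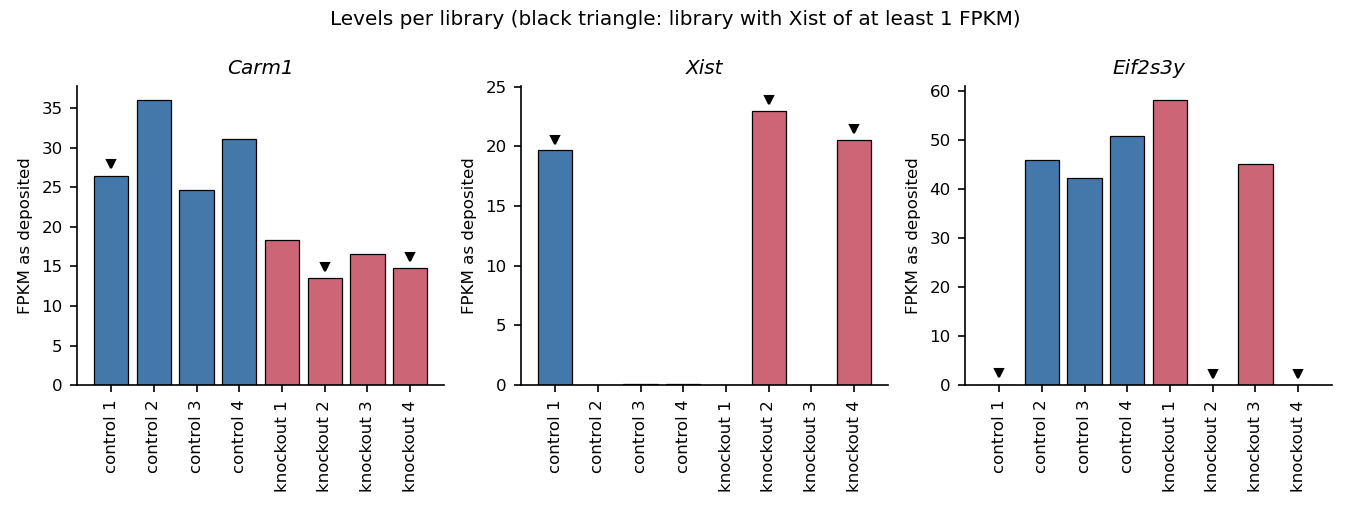
Bars give the FPKM as deposited of Carm1, Xist and the Y-linked gene Eif2s3y in each of the 8 libraries, with control libraries in blue, knockout libraries in red and a black triangle over libraries with Xist. Carm1 is at or above 24.7 FPKM in all controls and at or below 18.4 FPKM in all knockouts, while Xist is above 19.6 FPKM in control 1, knockout 2 and knockout 4 only, the libraries that lack Eif2s3y.

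Xist, the RNA that coats the inactive X chromosome of females, was present in 3 libraries although the animals are described as male. Control 1, knockout 2 and knockout 4 held 19.6, 22.9 and 20.5 FPKM of Xist, and each of the other 5 libraries held at most 0.0662 FPKM. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d showed the reverse arrangement: Eif2s3y lay between 42.3 and 58.1 FPKM in the 5 libraries without Xist and at or below 0.112 FPKM in the 3 with it. The type IIa myosin gene Myh2 followed the same arrangement, at 764, 1540 and 1535 FPKM in control 1, knockout 2 and knockout 4 and between 122 and 167 FPKM in the other 5. As 1 of these libraries is a control and 2 are knockouts, the counts of genes and of lists past the test are also given with presence of Xist as a covariate and for the 5 libraries without it, both chosen after the data were examined.

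Of 11096 genes tested with limma, 22 rose and 18 fell in the knockout at an adjusted p under 0.05. Among the genes that fell were Myh8, the perinatal myosin heavy chain, from 7.64 ± 3.43 to 1.20 ± 0.314 scaled FPKM, and Dhrs7c, a short-chain dehydrogenase of the sarcoplasmic reticulum, from 347 ± 30.6 to 135 ± 36.4 (mean ± SD, n = 4 each). Their log2 differences were -1.90 (SE 0.25, adjusted p = 0.0406) and -1.40 (SE 0.20, adjusted p = 0.0434). Fbp2, the muscle fructose-1,6-bisphosphatase, fell from 68.7 ± 16.9 to 31.8 ± 4.03 scaled FPKM, and Asb10, a suppressor-of-cytokine-signalling-box protein, fell by 1.01 on the log2 scale. The selenoproteins Gpx1, a glutathione peroxidase, and Msrb1, a methionine sulfoxide reductase, fell from 72.7 ± 6.58 to 39.7 ± 3.83 and from 190 ± 15.4 to 109 ± 19.8 scaled FPKM. The iron exporter Slc40a1 fell by 0.89, the docking protein Dok5 by 0.84, the adhesion protein Cntnap2 by 0.90, Nudcd3 by 0.70, the zinc-finger gene Zfp612 by 0.58 and Jph1, which ties the sarcoplasmic reticulum to the transverse tubule, by 0.54 on the log2 scale.

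The 12 largest increases were of smaller absolute size than the decrease of Myh8. Cstad rose from 0.928 ± 0.409 to 3.46 ± 1.04 scaled FPKM, with a log2 difference of 1.21 (SE 0.19, adjusted p = 0.0487), and Cyp4f39, a cytochrome P450 of the fatty acid hydroxylase family, from 8.54 ± 0.625 to 19.8 ± 4.84, with a log2 difference of 1.10 (SE 0.16, adjusted p = 0.0434). Inca1, which binds cyclin A1 and its kinase, rose by 0.96, the endonuclease subunit Eme2 by 0.85, the actin-binding Avil by 0.84 and the centrosomal Lrrcc1 by 0.80 on the log2 scale. Isoc2b went from 7.81 ± 0.836 to 14.2 ± 0.616 scaled FPKM and the acetyltransferase Sat2 from 5.08 ± 0.257 to 9.50 ± 1.79. Phc1, a polycomb group gene, rose by 0.75, D3Ertd751e by 0.67, the ubiquitin ligase adaptor Klhl22 by 0.64 and the actin-binding Dbnl by 0.60 on the log2 scale. Of the 40 genes, 8 had clone-type or microRNA names, which the naming rule skips, 4 higher and 4 lower. The largest decrease of the 40 was among these 8: it is listed as Mir214, singled out after its values were seen, but at a position on chromosome 1 that spans most of the gene Dnm3 and not the microRNA alone, so no value is given for it.

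All 40 genes had no overlap between the 4 control and the 4 knockout values, which held for 8.31% of the genes tested and would hold for 2.86% by chance. As the 40 were selected on these same values, their separation is no further support for them. With Xist as a covariate 223 genes passed, 121 higher and 102 lower, among them all 40. In the 5 libraries without Xist alone limma called 1 gene, AA465934, which is not among the 40, with 1321 genes at an unadjusted p under 0.05. There the filter still asked for at least 4 libraries, now out of 5, which left 10641 genes. With that stricter filter and fewer libraries the count is not comparable with 40. Without control 1, 2, 3 or 4 the count of 40 became 9, 6, 4 or 2, and without knockout 1, 2, 3 or 4 it became 6, 12, 27 or 4. On FPKM without scaling 36 genes were higher and 13 lower.

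**Figure D2:**
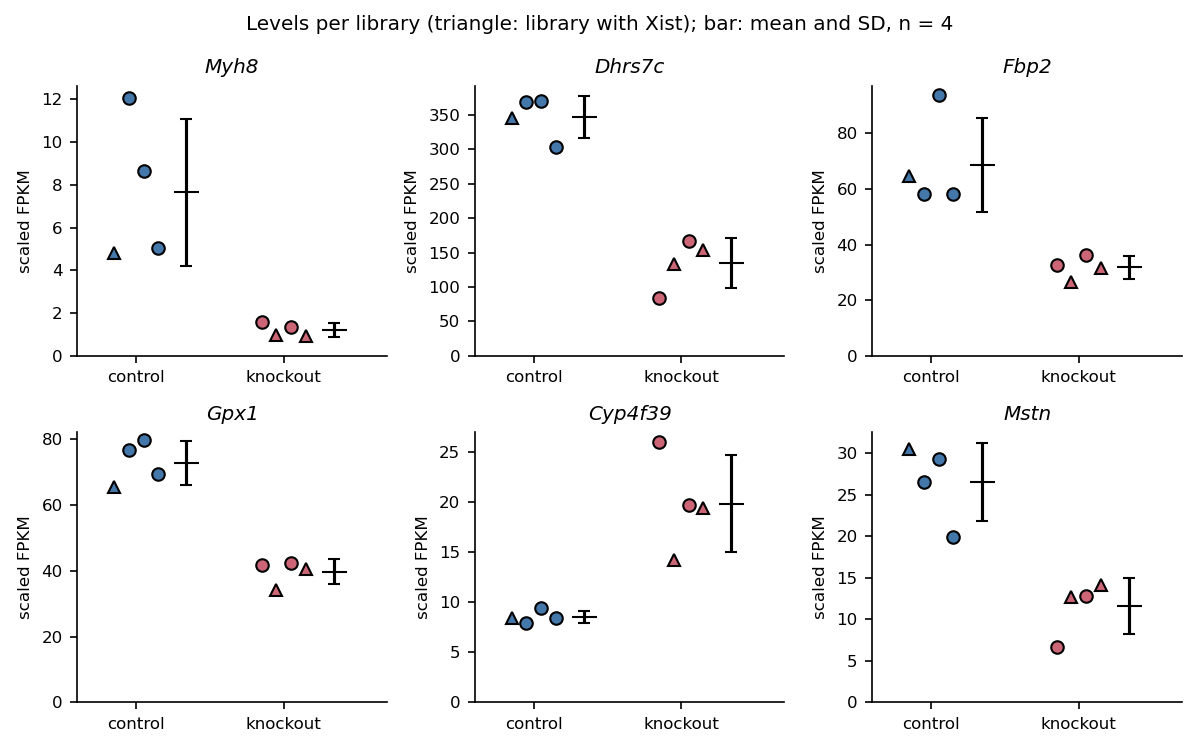
Points give scaled FPKM of 6 genes in each library, with control in blue, knockout in red, triangles for the 3 libraries with Xist and a bar for the mean and SD (n = 4). Dhrs7c averages 347 in controls and 135 in knockouts, and Mstn, past the test only with Xist as a covariate, averages 26.6 and 11.6.

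**Figure D3:**
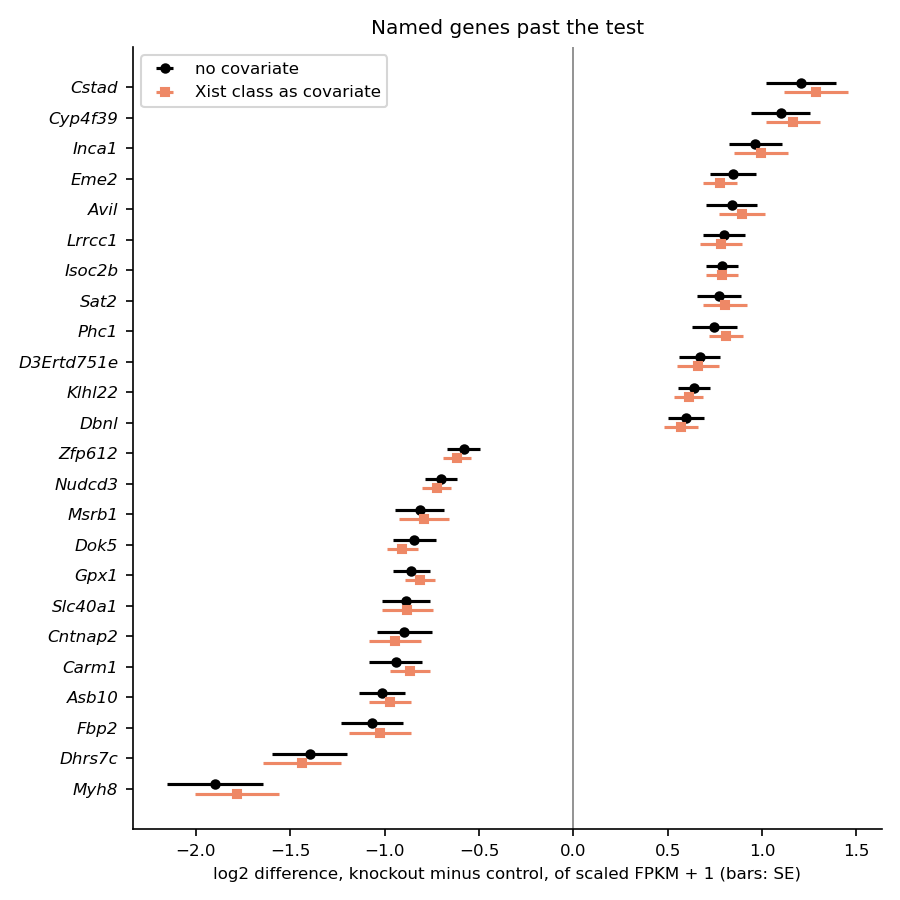
Points give the log2 difference (knockout minus control) of scaled FPKM + 1 for Carm1 and the named genes with the largest changes, with bars for the SE, in black without and in orange with Xist as a covariate. Myh8 stands at -1.90 and -1.78 and Cstad at 1.21 and 1.29 in these fits.

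Genes of respiratory complexes I to V, of the tricarboxylic acid cycle and of glycolysis were lower in the knockout as groups, although single members seldom passed. The lists of fatty acid oxidation, of glycogen, of mitochondrial dynamics and of AMPK did not pass at the settings fixed for the comparison (adjusted p 0.114, 0.114, 0.763 and 0.597). Of 39 lists tested with camera at a preset correlation 12 passed, 1 higher and 11 lower, and with an estimated correlation 0 passed (0 at an unadjusted p under 0.05). With Xist as a covariate 13 passed, 10 of them shared with the 12, and in the 5 libraries without Xist 8 passed, 6 of them shared. With an estimated correlation the smallest adjusted p was 0.61 in the first of these fits and 0.799 in the other. All 37 tested genes of respiratory complex I were lower, with a median log2 difference of -0.23, as were 35 of 36 genes of complexes II to V, with a median of -0.20, and 18 of 21 genes of the tricarboxylic acid cycle, with a median of -0.14. No member of these 3 lists passed over all genes or adjusted over the list alone. The members with the smallest p were Ndufb5 at -0.38, Ndufa13 at -0.37, Atp5g1 at -0.40, Atp5o at -0.31, Fh1 at -0.26 and Mdh2 at -0.29 on the log2 scale. In glycolysis 14 of 17 genes were lower, with a median of -0.33; Fbp2 fell over all genes, and Fbp2, the lactate dehydrogenase subunit Ldha at -0.57 and the glucose transporter Slc2a4 at -0.40 passed adjusted over the list alone. The adjusted p from camera, which compares a list with all other genes, was 1.06e-07 for complex I, 1.98e-06 for complexes II to V, 0.00998 for the tricarboxylic acid cycle and 0.000125 for glycolysis. With an estimated correlation the adjusted p was 0.634 for each of these 4 lists. After trends on transcript length, GC content and mean level had been removed, the 73 genes of complexes I to V had a median of -0.06, against -0.21 before. The lists of complexes II to V and of the tricarboxylic acid cycle, with medians of -0.04, did not pass (adjusted p 0.364 and 0.466). The tricarboxylic acid cycle list also did not pass in the 5 libraries without Xist, at -0.09 (adjusted p = 0.153), without control 1 or knockout 1, at -0.08 in both (0.227 and 0.143), or with quantile normalization, at -0.02 (0.496), where complexes II to V stood at -0.05 (0.0837).

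The 13 higher of 15 slow-fibre contractile genes had a list median of 0.53 and the 11 lower of 12 fast-fibre contractile genes one of -0.34. The adjusted p from camera was 0.00757 and 0.00753, and 0.634 for both with an estimated correlation. None of their members passed over all genes or adjusted over the list alone. Tnnt1, slow troponin T, stood at 11.7 ± 4.30 in controls and 29.5 ± 18.1 in knockouts, Atp2a2, the slow calcium pump, at 11.1 ± 2.45 and 16.4 ± 2.28, and Mylpf, the fast regulatory light chain, at 27007 ± 5842 and 17792 ± 2550 scaled FPKM (mean ± SD, n = 4 each). With Xist as a covariate the slow-fibre list had a median of 0.24 and an adjusted p of 0.12, and in the 5 libraries without Xist the slow-fibre and fast-fibre lists had medians of 0.23 and -0.09 and adjusted p-values of 0.159 and 0.42. The slow-fibre list also did not pass without knockout 4, at 0.23 (adjusted p = 0.0817), or without scaling, at 0.61 (0.0582). The fast-fibre list did not pass without knockout 2, at -0.20 (0.0817), with quantile normalization, at -0.05 (0.496), or with trends removed, at -0.11 (0.107). Myosin heavy chain shares could not be formed as planned, because Myh4 was listed at 0 in 6 libraries and Myh1 at 0 in control 1. Over the 7 libraries with Myh1, Myh2 made up 7.22% ± 1.30 (SD, n = 3) of Myh1, Myh2 and Myh7 in controls and 27.5% ± 24.2 (SD, n = 4) in knockouts, with an exact permutation p of 0.371 (2-sided). Knockout 2 and knockout 4, which held Xist, stood at 46.3% and 50.6%, while knockout 1 and knockout 3 stood at 7.36% and 5.84%. Knockout 2 and knockout 4 are also the 2 libraries in which Myh4 had a value, 2937 and 3056 FPKM, and in which no gene had the low-data status that was given to between 5 and 10 genes in each of the other 6. With Myh4 in the sum their Myh2 share was 24.6% and 25.2%, and no such share can be formed in the others. Control 1, which also holds Xist, had 10 genes with the low-data status, so Xist as a covariate does not cover this difference. No fit left out knockout 2 and knockout 4 together, so its weight in the gene and list results was not tested.

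Genes of the extracellular matrix and markers of fibro-adipogenic cells, endothelium and smooth muscle were also lower as groups with a preset correlation, and their adjusted p was 0.634 for each with an estimated correlation. Tendon markers, which did not pass, had a median of 0.37. In the extracellular matrix list 25 of 28 genes were lower, with a median of -0.21, and the markers of fibro-adipogenic cells, of endothelium and of smooth muscle had medians of -0.32, -0.16 and -0.28, with 12 of 13, 13 of 13 and 11 of 11 genes lower. No member of these 4 lists passed over all genes or adjusted over the list alone; Sparc stood at -0.46, Col5a1 at -0.51, Smoc2 at -0.58, Dpt at -0.52, Esam at -0.20, Cdh5 at -0.25, Cnn1 at -0.40 and Kcnj8 at -0.28 on the log2 scale. Their adjusted p from camera at the preset correlation was 0.00231, 0.0179, 0.0241 and 0.00154. Per library the mean over the fibro-adipogenic, endothelial and smooth muscle markers differed by -0.26 (SE 0.203), -0.15 (SE 0.104) and -0.27 (SE 0.104) on the log2 scale, with 2-sided exact permutation p-values of 0.257, 0.2 and 0.0571. The immediate early genes had a median of -0.26, with 13 of 17 lower and an adjusted p of 0.0123 (0.634 with an estimated correlation). Over that list alone Nr4a1 at -1.14, Klf2 at -0.59 and Myc at -0.70 passed, and none passed over all genes. The cytosolic ribosome list had a median of -0.10, with 26 of 28 lower and an adjusted p of 0.00998, but its direction in camera turned under quantile normalization, and with an estimated correlation its adjusted p was 0.671.

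Part of these calls depended on the libraries and on the fit. The endothelial list had a median of -0.11 and an adjusted p of 0.104 with Xist as a covariate, and -0.09 and 0.236 in the 5 libraries without Xist. In those 5 libraries the immediate early and ribosome lists, at -0.16 and -0.06, also did not pass (adjusted p 0.111 and 0.153). The matrix and fibro-adipogenic lists passed there at -0.42 and -0.54 (1.69e-06 and 0.000231, and 0.799 for both with an estimated correlation). The endothelial list did not pass without control 3, control 4, knockout 1 or knockout 2, at -0.14, -0.15, -0.14 and -0.06 (adjusted p 0.0607, 0.0548, 0.108 and 0.169). The fibro-adipogenic list did not pass without control 3, control 4 or knockout 3, at -0.19, -0.17 and -0.17 (0.0634, 0.0765 and 0.29). The matrix list did not pass without knockout 3, at -0.12 (0.146). The immediate early list did not pass without control 1 or control 3, at -0.12 and -0.21 (0.207 and 0.0607), or among genes with a mean of at least 5 FPKM (0.0706). The ribosome list did not pass without control 3 or knockout 2, at -0.03 and -0.06 (0.39 and 0.135), or without scaling, at -0.02 (0.0582). With quantile normalization the fibro-adipogenic and endothelial lists had adjusted p-values of 0.0652 and 0.163, and with trends removed 0.0752 and 0.159, where the ribosome list stood at 0.02 (0.719).

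**Figure D4:**
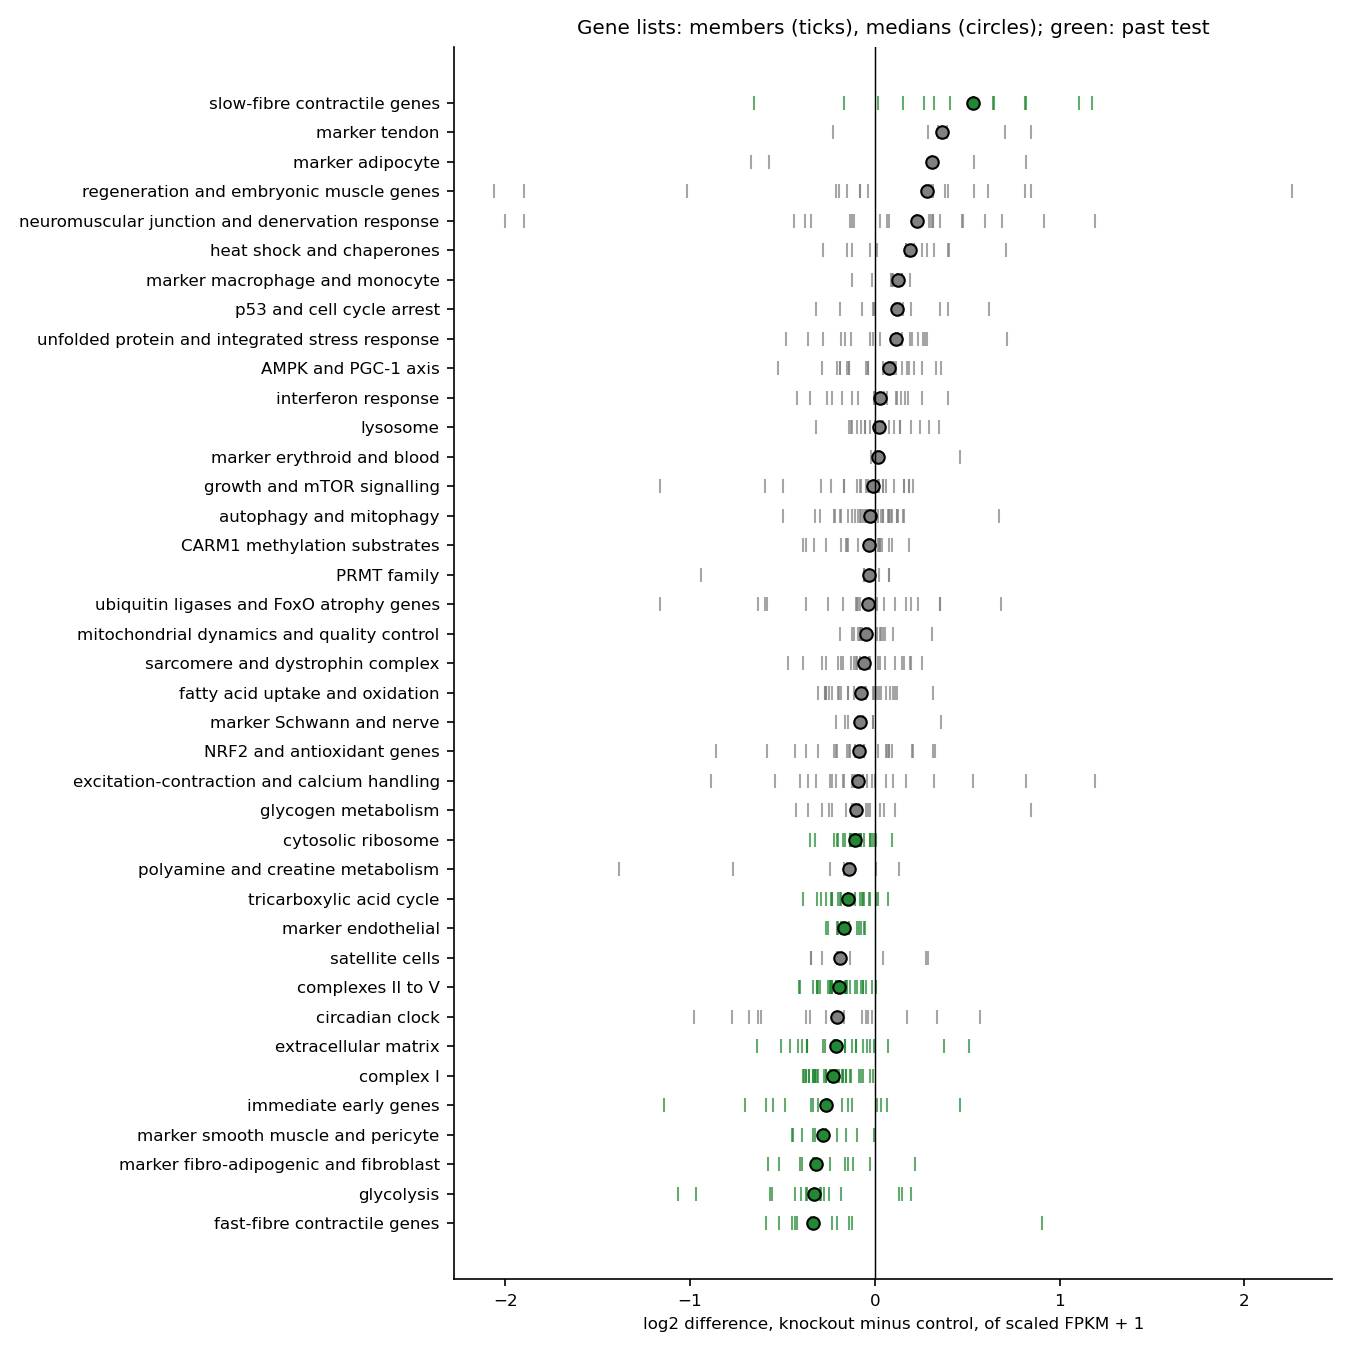
Ticks give the log2 difference (knockout minus control) of scaled FPKM + 1 of each tested member of the 39 tested lists, and circles the list medians, in green where the adjusted p from camera was under 0.05 and in grey elsewhere. The slow-fibre list, with a median of 0.53, is the 1 green list above 0, and 11 green lists lie below 0.

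The remaining lists did not pass camera at the settings fixed for the comparison, and most of their members did not pass either. Carm1 was the 1 gene called of 7 in the PRMT family, where the list median was -0.03. In the excitation-contraction list, with a median of -0.09, Jph1 fell, in the list of antioxidant genes, with a median of -0.08, Gpx1 fell, and in the neuromuscular junction and the regeneration lists, with medians of 0.23 and 0.28, Myh8 fell. Adjusted over the list alone, the acetylcholine receptor subunits Chrnd at 0.69 and Chrnb1 at 0.59, Hdac4 at 0.47 and Fgfbp1 at -2.0 also passed in the neuromuscular list, and H19 at 2.26 in the regeneration list. Mstn, the muscle growth inhibitor myostatin, passed over the lists of atrophy genes and of growth signalling alone, at -1.16, with an adjusted p of 0.0764 over all genes and 0.0304 with Xist as a covariate. The AMPK subunit Prkab2 at -0.53 and the phosphorylase kinase subunit Phka1 at -0.36 passed only over their lists alone in the fit without the covariate. The same held for Sdf2l1 at 0.71, the T-cell gene Cd3e at 1.36, and Car3 at 0.82 and Fasn at 0.54 of the adipocyte marker list. Without knockout 1 Car3 stood at 0.53 and Fasn at 0.34, and the adipocyte markers, relative to their mean over the 8 libraries, were at 0.78 in knockout 1 and between -0.32 and -0.10 in the other 3 knockouts. The atrophy, growth and AMPK lists had medians of -0.04, -0.01 and 0.08. In those of autophagy, the lysosome, fatty acid oxidation and mitochondrial dynamics the medians were -0.03, 0.02, -0.08 and -0.05, and in those of glycogen, satellite cells, the sarcomere and the clock they were -0.10, -0.19, -0.06 and -0.20. Heat shock, unfolded protein, p53, interferon, CARM1 substrate and polyamine genes had medians of 0.19, 0.11, 0.12, 0.03, -0.03 and -0.14. The interferon list had a mean of -0.01 and a lower direction in camera, against the sign of its median. In the 5 libraries without Xist it passed in the higher direction, with a median of 0.21 (adjusted p = 0.0131), and the glycogen list passed in the lower, with -0.21 (adjusted p = 0.0166). With an estimated correlation the adjusted p was 0.799 for both. Markers of macrophages, adipocytes, blood, Schwann cells and tendon had medians of 0.12, 0.31, 0.02, -0.08 and 0.37, and the proliferation and lymphocyte lists, with 4 and 2 tested genes, were too small for camera.

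Some of these lists passed camera under other settings, all with the preset correlation. With an estimated correlation 0 of the 39 lists had passed in the fit of all 8 libraries. Heat shock genes passed in the higher direction with trends removed, at a median of 0.25 (adjusted p = 0.00958), and with quantile normalization, at 0.26 (0.0121). They also passed among genes with a mean of at least 5 FPKM, at 0.19 (0.0379), and without control 3 or knockout 1, at 0.24 and 0.27 (0.00516 and 0.0123). Tendon markers passed in the higher direction with no filter, at 0.29 (adjusted p = 0.0362), and without control 4 or knockout 4, at 0.60 and 0.50 (0.0123 and 0.0456). Macrophage markers did so without control 4 or knockout 3, at 0.23 and 0.27 (0.0242 and 0.0168). The tendon markers, relative to their mean over all libraries, were at -0.90 in control 1 and 0.74 in knockout 1. In each of the other libraries they lay between -0.16 and 0.31. Fatty acid oxidation passed in the lower direction with no filter, at -0.08 (adjusted p = 0.0328), and without control 4, at -0.18 (0.00141). The excitation-contraction list did so with no filter, at -0.09 (0.0267), and without knockout 3, at -0.12 (0.0418). The clock genes passed in the lower direction without control 3, at -0.43 (adjusted p = 0.00921), and with the replicate block, at -0.20 (0.0483). Also lower were satellite cell genes with no filter, at -0.16 (0.0377), polyamine genes without control 1, at -0.21 (0.00789), and CARM1 substrates among genes with a mean of at least 5 FPKM, at -0.15 (0.0351).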

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

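In this part the tests of escape genes, genotype labels, depth, the Xist covariate, other cell types and chromosome 11 were chosen after the results were seen. The test of length, GC and level was chosen after the data were examined and before its own result was seen. A library was singled out where its gap to the nearest of the other 3 libraries of its group exceeded 0.829 of the group's range. Of 204 groups of 4 values 15 were singled out, and chance alone would give about 10.2. The measures included Xist, Eif2s3y, Ddx3y, Uty, Kdm5d and Myh2, which the naming rule does not give, and each of them singled out control 1. The count of 15 is therefore no evidence of an excess over chance.

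In controls, control 1 stood apart for Xist (gap 0.981 of the range), Eif2s3y (0.987), Ddx3y (0.863), Uty (0.984), Kdm5d (0.900) and Myh2 (0.879); its Myh2 level was 782 scaled FPKM against 141 to 173 in the other 3 controls. Control 1 was also the highest control for Klhl22 at 15.1 against 13.4 to 13.5 scaled FPKM (0.926), Zfp612 at 5.58 against 4.32 to 4.50 (0.839) and Pcna at 17.1 against 12.8 to 13.2 (0.874). Control 3 was the highest control for Mylpf at 35720 against 23250 to 24714 scaled FPKM (0.858). In knockouts, knockout 1 was the lowest for Mstn at 6.66 against 12.6 to 14.2 scaled FPKM (0.845), knockout 2 the highest for D3Ertd751e at 5.10 against 3.76 to 3.88 (0.901), and knockout 3 the highest for Mdh2 at 1511 against 1127 to 1175 (0.859) and the lowest for Col5a1 at 2.36 against 3.32 to 3.48 (0.873). Knockout 3 also had the fewest genes at 1 FPKM or more, 10868 against 11203 to 11221 (0.949).

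Control 1, knockout 2 and knockout 4 held Xist and nearly no Y-linked RNA. All 4 genes known to escape X inactivation, Kdm6a, Kdm5c, Ddx3x and Eif2s3x, were higher in each of these 3 libraries than in each of the other 5. Ddx3x, for example, lay between 65.8 and 77.5 against 32.8 to 39.1 scaled FPKM. Eif2s3y was at most 0.114 against at least 46.7 scaled FPKM. These values argue against male tissue in the 3 libraries, and female animals in place of male would give them. Sex is then unbalanced between the genotypes, with control 1 against knockout 2 and knockout 4. Exchanged genotype labels are argued against by Carm1, which lay on the side of its own genotype in 3 of the 3 libraries, and a difference in depth by the relative depth of 2 of the 3 libraries, which lay inside the range of the other 5. Whether animals or samples from elsewhere were substituted within a genotype stays open.

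The 73 genes of complexes I to V were lower in knockouts, with a median log2 difference of -0.21. Removing trends on length, GC content and level left a median of -0.061 (SE 0.017, SD of genes 0.114 against 0.103 before), between the bounds of -0.05 and -0.1 set beforehand. How much of the shift such trends could carry therefore remains open. Complexes II to V lost their call because the median shrank to -0.04, and complex I passed at -0.10 with the preset correlation (adjusted p = 0.00484). Before the removal, the adjusted p from camera with an estimated correlation was 0.634 for both lists. The median of the 73 genes before the removal lay below all 10000 random lists matched on length and level, whose median was -0.09. Those lists were drawn as if genes varied independently. The estimated correlation among genes was 0.60 in complex I and 0.56 in complexes II to V, so the random lists cannot show that the shift exceeds chance. Presence of Xist as the only source is argued against by a median of -0.15 in the 5 libraries without it. With an estimated correlation, however, neither list passed camera there (adjusted p 0.799 for both). With genotype held, complex I and complexes II to V had medians of -0.13 and -0.04 in libraries with Xist relative to those without. Neither passed camera in that contrast (adjusted p 0.179 and 0.709), so a part of the shift can still come from it. A lower share of muscle fibres would raise markers of every other cell type alike, but 3 of 4 marker lists had medians below -0.1; per library the largest of these shifts, of smooth muscle by -0.27 (SE 0.104), had an exact permutation p of 0.0571 (2-sided), the shifts of tendon, adipocyte and macrophage markers, 0.39 (SE 0.325), 0.08 (SE 0.304) and 0.10 (SE 0.223), had exact p-values of 0.4, 0.8 and 0.714, and the mean of the 2 neutrophil and lymphocyte markers, 0.79 (exact p = 0.0286), rests on Cd3e at 1.36 with S100a8 at 0.22, so that explanation stays open, as does the choice between loss of Carm1 and presence of Cre.

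Of the genes called with Xist as a covariate, 27 of 975 tested on chromosome 11 (2.77%) and 196 of 10121 elsewhere (1.94%) passed. A local effect of the transgene or of a linked strain segment could give such an excess, but Fisher's exact test gave a 2-sided p of 0.0927. Over all chromosomes 69 pairs of called genes lay within 1 Mb, against a median of 45 for random genes, and 10 of 2000 random draws gave as many, so the 2 parts of the test differ and the explanation stays open. The insertion site of the transgene is not given in the sources used here.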

How the results depend on the processing

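Alternatives using the presence of Xist, the removal of length, GC and level trends and the myosin share over 3 genes were chosen after the data were examined. The count of 40 genes became 8 without a filter, 15 with a mean of at least 5 FPKM, 103 with array weights, 223 with Xist as a covariate, 1 in the 5 libraries without Xist and 1 within the 3 with it (Rps27, a comparison with control 1 alone), and lay between 2 and 27 with 1 library left out; with the covariate it lay between 5 (without control 1) and 191. The cause was not tested except that fewer libraries enter some fits. The 12 lists became 7 with quantile normalization, 7 with trends removed and 0 with an estimated correlation (camera, 0 at an unadjusted p under 0.05). With the replicate block, limma called 0 genes (1314 at an unadjusted p under 0.05). The Carm1 difference of -0.94 then had an exact p of 0.125 over sign changes of the 4 differences between equal numbers. Carm1 was lower in the knockout of every number, and that p is the smallest such a test can give. Of the 4 control libraries, 2 correlated best with the knockout of their own number, and the correlations of equal numbers were -0.43, -0.19, 0.35 and 0.19. Control 1 correlated at 0.48 and 0.37 with knockout 2 and knockout 4, which like it hold Xist, and at -0.43 and -0.38 with knockout 1 and knockout 3. Such structure can hide a pairing, so whether the numbers pair the animals stays open. In the 5 libraries without Xist the Carm1 difference was -0.80 (exact p = 0.1, the smallest 10 assignments can give) and the difference in Myh2 share -0.62 percentage points in place of 20.3. The ribosome list turned in camera under quantile normalization, with a median of -0.00298. Of the genes given as values, with 1 library left out C1qa lay between -0.00931 and 0.348 and S100a8 between -0.0436 and 0.487. C1qa at -0.0100 and Cd163 at -0.0124 turned in the 5 libraries, and Pcna at -0.0509, S100a8 at -0.376, Odc1 at 0.0392, Smoc2 at 0.0538, Dpt at 0.0956 and Pmp22 at 0.0327 within the 3 libraries. Over the 92 named genes, settings other than left-out libraries gave 851 values on the same side of the threshold, 120 no longer past it and 5 newly past it. With 1 library left out these were 551, 178 and 2. Most values on the same side belong to named genes that had not passed. Those that had passed were mostly lost with 1 library left out. Without control 2, 0 of them stayed past the threshold and 25 did not. Without knockout 3, where the most stayed, 10 did and 15 did not. Over the 12 lists 91 stayed on the same side and 28 did not, and with 1 library left out 80 and 16. No gene shared a symbol, so keeping loci separate moved nothing, and the log2 ratio to Myh4 and the planned 4-gene share had no value. Read counts are not known, so what depth limits could not be tested.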

Other observations

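The tests of splits within the presence of Xist, of libraries with against without Xist and of imprinted genes were chosen after the results were seen, and so were the genes named here. With Xist as a covariate, genes past the test beyond the 40 included the carboxylesterase Ces1d, at 31.2 scaled FPKM in controls and 7.14 in knockouts (log2 difference -1.93, adjusted p = 0.0377), the cytokine gene Il15 at 14.5 and 8.51, and the stress gene Gadd45b at 43.0 and 24.9. Higher were the lipogenic regulator Srebf1 at 8.62 and 17.4, the carbonic anhydrase Car2 at 7.99 and 17.8, and the DNA demethylase Tet2 at 2.69 and 5.76 scaled FPKM. Without control 1, 2, 3 or 4 that fit called 5, 59, 191 or 25 genes, and without knockout 1, 2, 3 or 4 it called 19, 47, 93 or 62. The lists of fatty acid oxidation, with a median of -0.15, of glycogen, with -0.14, and of tendon markers, with 0.52, passed camera with the covariate (adjusted p 0.00323, 0.0338 and 0.0332) and not in the fit of the 8 libraries without it at the fixed filter. With an estimated correlation the adjusted p was 0.61 for each. Tendon markers lay furthest from their mean over all libraries in control 1 (-0.90) and knockout 1 (0.74). The glycogen list also passed in the 5 libraries without Xist (adjusted p = 0.0166, and 0.799 with an estimated correlation).

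Clock genes differed between libraries of 1 genotype: Arntl lay between 1.25 and 13.3 FPKM and Dbp between 28.0 and 161 FPKM over the 8 libraries. Control 3, knockout 1 and knockout 3 had the highest Arntl and the lowest Dbp, the latter at 29.4, 28.0 and 40.1 FPKM. Each of the others had at most 3.47 FPKM of Arntl and at least 60.7 FPKM of Dbp. In the 5 libraries without Xist, every knockout but only control 3 of the controls had this pattern. Its weight in the fit of those 5 libraries was not tested. H19 lay between 173 and 819 FPKM in controls and between 621 and 2265 FPKM in knockouts.

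Of the 35 splits of the 8 libraries into 4 and 4, 2 gave 40 or more genes, so chance is not excluded for that count. The other was the split of control 1, control 4, knockout 2 and knockout 4 from the rest, with 917 genes, which gathers the 3 libraries with Xist and control 4 and points to a structure of the samples; the 4 other splits that gather these 3 libraries gave 0, 0, 5 and 3 genes. With genotype held, 1381 genes, 1328 of them autosomal, differed between libraries with and without Xist. In that contrast the slow-fibre, fatty acid oxidation, fast-fibre and polyamine lists passed camera, with medians of 0.59, 0.31, -0.47 and -0.29. Their adjusted p was 0.000622, 0.000876, 0.00464 and 0.0102. With an estimated correlation it was 0.226 for the slow-fibre list and 0.991 for the other 3. For the gene lists 16 of the 35 splits gave 12 or more, up to 18, so chance is not excluded there either. With Xist as a covariate, 1 of the 30 splits that keep the genotype numbers within libraries with and without Xist gave 223 genes, the real one. The highest of the others gave 5, so no other split came near that count. The real split is always 1 of the 30, and the covariate and this test were chosen after the results were seen. Chance is therefore made less likely for that count and is not excluded.

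Among genes called with the covariate were the imprinted genes H19 and Peg3, higher, and Rian, Meg3 and Asb4, lower, and a candidate explanation is a coordinated change of imprinted genes. The list of 46 imprinted genes used to test it was written after these 5 had been seen, and 6 of its 25 tested members were called, so that count is no evidence. Among the 20 tested members not seen before, 1 was called, Airn, whose listed position is that of Igf2r, against 217 of 11071 other genes, with a 2-sided Fisher's exact p of 0.328. The bound for rejecting the explanation was set when that call was already known, and the exact binomial interval of the share reaches up to 24.9%, so the test leaves it open.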
